A study of Mus musculus with 4 samples.

How the data were processed

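Gene expression of single cells was measured in 4 libraries of inner ear organoids made from a mouse embryonic stem cell line with a nuclear GFP reporter of Atoh1, 1 library for each of day 16, day 20, day 21 GFP high and day 21 GFP low. Per the labels, whole organoids were dissociated and sorted on GFP, and the cells were loaded on a 10x Genomics chip; the labels' description speaks of single nuclei, while the protocol speaks of cells. The deposited tables hold raw UMI counts per gene and barcode, without normalisation, as whole numbers. Per the file headers the tables were written by Cell Ranger 6.1.2, while the authors' processing notes list Cell Ranger 6.1.0, Seurat 4.0.6 and genome build mm10. The gene annotation and the use made of Seurat are not given in the sources used here. The tables list 32289 genes, including a gene named Egfp for the reporter, and 78 of them share a symbol with another gene and were kept apart by identifier. Coordinates are those of GENCODE M21 on GRCm38, which held 32158 of the 32289 identifiers and 377 of 377 named or listed genes.

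The tables held 4277, 5619, 3844 and 4467 barcodes for day 16, day 20, GFP high and GFP low. Barcodes with fewer than 1000 detected genes (588, 1062, 145 and 322) or more than 15% mitochondrial UMIs (395, 40, 222 and 491) were left out. Scrublet, as built into Scanpy 1.11.5, scored doublets, and in each library the highest scores were removed at a rate of 0.8% per 1000 barcodes (120, 205, 109 and 137 cells), since its automatic threshold called 9, 95, 15 and 16. The kept cells numbered 3376, 4348, 3435 and 3686, with median detected genes of 3958, 2718, 5997 and 5180 and median mitochondrial shares of 2.60%, 0.922%, 5.06% and 3.42%. These depths and cell numbers set the intervals.

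Kept cells of all libraries were clustered together without integration: counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen by dispersion within libraries, scaled values were limited at 10, and 30 principal components and 20 neighbours gave a graph that was clustered with the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. Of 28 clusters 19 were named. A marker was raised where its CPM plus 5 was at least 4 times that of the median cluster, and a cluster took the name of a cell type when at least 50% of its measured markers, and at least 3, were raised. A list needed 5 or more markers at 20 CPM in some cluster to give a name. Where a second list was also raised, the name needed more markers among the 25 leading genes than each other list. A cluster stayed unnamed when another list had more markers among its 10 leading genes, when other lists together outnumbered the name among the 25 by 2 to 1, when 3 or more of the 10 were crystallin genes, or when its depth was low and no marker led. This naming rule was set after the clusters had been seen. A name means likeness in these markers.

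Counts were summed over the kept cells, or over the cells of a class, in each library. They were divided by the total of the same cells and scaled as CPM. Ratios carry an exact conditional binomial 95% interval, levels an exact Poisson interval and shares an exact Clopper-Pearson interval. The comparisons were GFP high over GFP low at day 21 and day 20 over day 16, each over all cells and within hair-cell-like cells, and GFP high over GFP low within supporting-cell-like cells. With 1 library per group there is no test across samples, so no p-values were computed, and none were made from cells. A member of a list was called higher or lower when its CPM ratio was 2 or more either way and its counting interval excluded 1, a rule of size. The value of a list is the median of log2((CPM + 1)/(CPM + 1)) over members at 10 CPM or more in either library, with an interval from 1000 Poisson redraws and its percentile among 10000 random lists of equal size and like mean expression. There were 28 lists, 15 of cell type markers and 13 of pathways and hair cell programmes. Named genes were Atoh1, the 10 with the highest and the 10 with the lowest CPM ratio among genes at 50 CPM or more in either library and 30 or more UMIs over both, without mitochondrial and ribosomal protein genes, and up to 4 members of each list at 20 CPM or more with the largest absolute log2 ratio. Egfp and Ccer2, and Dazl, Gfap, Aqp4 and other leading genes of clusters, were chosen after their values were seen. Cells positive for Mki67 or Top2a were counted after thinning each cell to 3000 UMIs, which left out 333, 555, 31 and 93 shallower cells. TMM factors came from edgeR 4.0.16 in R 4.3.3. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

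Groups, comparisons, the 28 gene lists, cell filters, the rule for named genes and the first set of alternatives were chosen before the data were examined. A Merkel cell list, used only under Other observations, was added afterwards. The alternatives were other cell filters, other scalings, another pseudocount, no CPM minimum, other clustering settings, a class set by marker genes and other thinning depths, and 18 more were added later.

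The ratios and list values were tested on simulated data with the depths of each comparison, in which 200 genes were changed by 1.5-, 2.5- or 4-fold. For GFP high over low in all cells, day 20 over day 16 in all cells, both within hair-cell-like cells and GFP high over low within supporting-cell-like cells, in this order, intervals held the true ratio in 95.0%, 95.3%, 95.2%, 95.2% and 95.2% of genes. The size rule called 0, 0, 0, 10 and 0 of the 8887 to 9798 unchanged genes, 0%, 0%, 0%, 1.23% and 0% of the 1.5-fold changes, 100%, 100%, 100%, 93.5% and 97.1% of the 2.5-fold changes, and 100% of the 4-fold changes in each comparison. Intervals of unchanged lists held the true median in 100%, 97.5%, 98.5%, 98.5% and 99% of lists, and their mean percentile ranged from 45.0 to 51.5. The simulations hold counting error alone. Aldoa was not found by its symbol and was left out of its list. RNA from near-identical genes, such as Hspa1a and Hspa1b, cannot be assigned with certainty.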

Results

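RNA of single cells was measured with 10x Genomics droplet libraries in mouse inner ear organoids, aggregates of embryonic stem cells guided towards the tissue that forms the inner ear. The stem cell line carried nuclear GFP as a reporter of Atoh1, the transcription factor that starts hair cell formation. There were 4 libraries, 1 for each group: day 16, day 20, day 21 with high GFP signal and day 21 with low GFP signal. After filtering, the day 16 library held 3376 cells and 57364998 UMIs, and the day 20 library 4348 cells and 42325800 UMIs. The GFP high library held 3435 cells and 107308236 UMIs, and the GFP low library 3686 cells and 93416071 UMIs. Median UMIs per cell were 15226 at day 16, 8836 at day 20, 28868 in GFP high and 22221 in GFP low. No group had replicates, so no difference between libraries has a replicate check, and every interval, of Poisson counts or of exact Clopper-Pearson shares, covers counting error only. The labels name a GFP gate for the day 21 libraries alone, and the gate used at days 16 and 20 is unclear. The series asks what cell types these organoids can form, and the comparisons address which cells and genes differed between the gates and between the days.

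Cells fell into 28 clusters, of which 19 could be named from marker genes, and the libraries differed widely in make-up. Hair-cell-like cells, named from markers such as Pou4f3 and Myo7a of the sensory cells of hearing and balance, made up 65.0% of the GFP high library (2232 cells, 95% interval 63.4 to 66.6%). Their share was 22.4% in GFP low (824 cells, 21.0 to 23.7%), 5.66% at day 16 (191 cells, 4.90 to 6.49%) and 3.36% at day 20 (146 cells, 2.84 to 3.94%). Supporting-cell-like cells, the other main cell of a sensory epithelium, made up 18.1% of GFP low (667 cells, 16.9 to 19.4%) and 8.88% of GFP high (305 cells, 7.95 to 9.88%). They were 0.592% of cells at day 16 (20 cells, 0.362 to 0.914%) and 0.391% at day 20 (17 cells, 0.228 to 0.625%). Mesenchyme-like cells were the largest named class at day 20, with 47.2% of cells, against 28.1% at day 16, 1.31% in GFP high and 2.66% in GFP low. At resolution 0.5 the day 16 share was 18.8% and that of day 20 44.2%. The days differed in their mesenchyme-like clusters. Cluster 0 held 12 cells of day 16 and 1582 of day 20, cluster 18 held 307 and 23, and cluster 11 held 241 and 304. The shares are thus not those of 1 population. Neuron-like cells made up 23.2% at day 16, 6.72% at day 20, 5.85% in GFP high and 24.6% in GFP low. Epidermis-like cells ranged from 1.78% in GFP high to 8.26% at day 16 (5.60% with 4000 variable genes), where 89 cells (2.64% of the library) belonged to a cluster that also held Pou4f3 at 906 CPM and Atoh1 at 500 CPM. Neural-progenitor-like cells were 0.504% at day 16 and 3.08% at day 20, but 6.102% and 5.24% with 4000 variable genes and 0 of both with each library clustered alone. In their cluster 6 of 9 neural progenitor markers and 57.1% of neuron markers were raised. Of its leading genes Fabp7 and Pax6 are on the neural progenitor list, but Gfap, Aqp4, Sparcl1 and Bcan are not, so the name is loose. Pluripotent-like cells, led by Dppa5a and Pou5f1 together with the germ cell genes Stra8 and Dazl, were 1.81% at day 16, 1.82% at day 20, 0.320% in GFP high and 2.79% in GFP low. Their cluster also had 90% of mesenchyme markers raised, at a median of 2.04 times the library's median depth. In the day 16 and day 20 libraries only 1 of 7 pluripotent markers, Dppa5a, reached 10 CPM, and 10 cells held 98.8% of its day 16 UMIs. The name is thus poorly borne out at these days. At resolution 2.0 pluripotent-like cells were 14 cells at day 16 and 3 at day 20 in place of 61 and 79. In GFP high they were 1.02% at resolution 0.5 and 0 with each library clustered alone. The small classes of these days, and this class in GFP high, therefore have no firm size. Clusters without a name held 31.9% of cells at day 16, 34.5% at day 20, 16.3% in GFP high and 25.7% in GFP low. Among them, a cluster led by the cartilage genes Cnmd and Matn1 with the otic genes Oc90 and Tecta held 10.6% of GFP low and 6.75% of GFP high. A cluster with both hair cell and supporting cell markers raised, at a median of 52925 UMIs (1.86 times the library median), held 4.25% of GFP high and 0.136% of GFP low. Whether its cells are doublets was not tested. The hair-cell-like share at day 20 was 17.5% at a clustering resolution of 2.0 and 18.4% with 4000 variable genes, where cells of unnamed clusters rich in Ccer2 joined the class and the unnamed share fell to 20.1% and 17.9%, and that of day 16 was 3.40% with doublets kept. With each library clustered alone, supporting-cell-like cells were 9.39% of GFP low, and no cluster of day 16 or day 20 took the name.

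**Figure D1:**
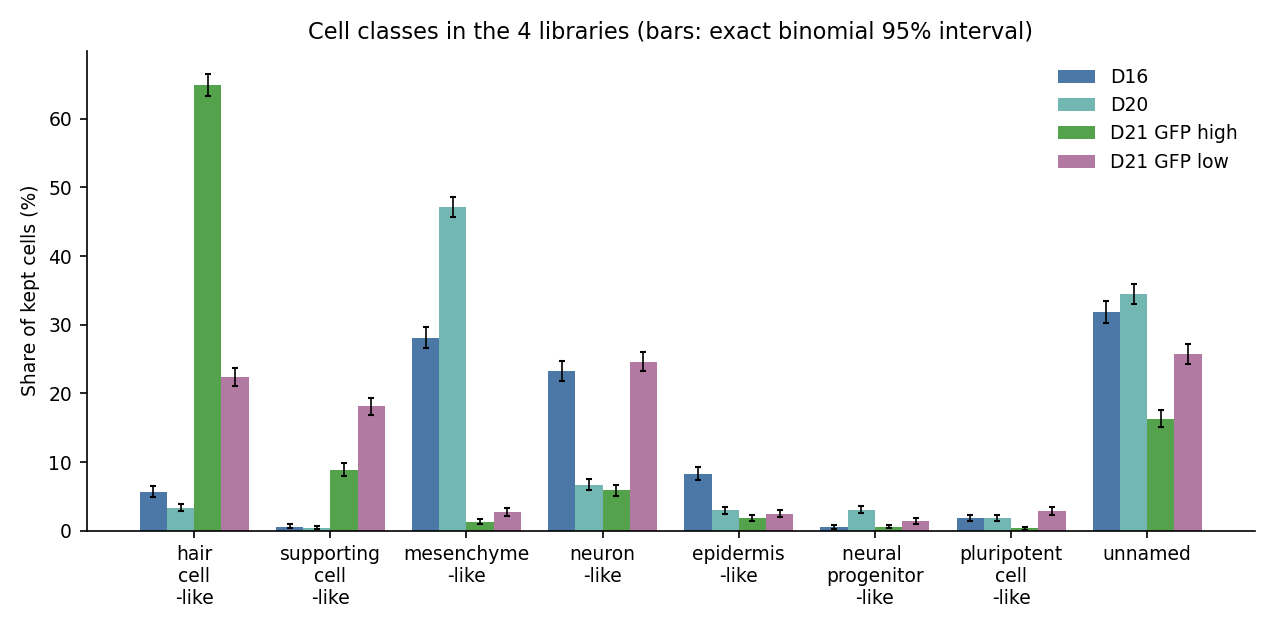
Share of kept cells in percent (vertical axis) for each cell class (horizontal axis) in the 4 libraries (colours), with exact Clopper-Pearson 95% intervals as bars. Hair-cell-like cells reached 65.0% in GFP high and 22.4% in GFP low, and mesenchyme-like cells 47.2% at day 20.

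At day 21, Atoh1 and 19 of 22 hair cell markers were higher in the GFP high library than in the GFP low library, while 7 of 13 neuron, 7 of 8 mesenchyme, 16 of 20 cell cycle and 6 of 6 pluripotent markers were lower. This comparison addresses what the GFP gate separated. Atoh1 (ENSMUSG00000073043, GRCm38 chromosome 6, 64729125 to 64731245, plus strand, protein coding) stood at 144.5 CPM (142 to 147; the UMIs of a gene scaled to the library total) in GFP high and 34.04 CPM (32.9 to 35.3) in GFP low, a log2 ratio of 2.09 (2.03 to 2.14). Reporter RNA, counted as Egfp and chosen after its values were seen, stood at 4860.0 and 1312 CPM. Among 22 measured hair cell markers 19 were higher, 0 lower and 3 neither, with a median log2 ratio of 1.82 (1.80 to 1.84). That median lay at percentile 100 of 10000 random lists of like expression, a description of these libraries alone.

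Members of several hair cell programmes were higher in GFP high. Of 23 measured genes of the hair bundle and mechanotransduction, which build and gate the bundle that senses sound and motion, 19 were higher and 4 neither (median log2 ratio 1.28, percentile 100). Lhfpl5, a part of the transduction channel complex, stood at 539 against 99.2 CPM, Grxcr1 at 109 against 17.5 CPM and Myo3b at 78.1 against 15.5 CPM. Of 12 hair cell transcription factors 6 were higher and 6 neither (median 0.87, percentile 100). Pou4f3 (chromosome 18, 42394539 to 42397249, plus strand), needed for hair cell survival, had 441 against 121 CPM, Lhx3 171 against 44.4 CPM and Barhl1 61.1 against 8.59 CPM. Synapse genes were split, with 6 of 14 higher and 8 neither (median 0.11, percentile 86.5), and the highest ratio among those named was that of Otof (chromosome 5, 30367062 to 30461932, minus strand), the calcium sensor of hair cell transmitter release, at 792 against 128 CPM. Genes listed for vestibular type I and striolar hair cells had 4 higher, 1 lower and 5 neither (median 0.60), with Ocm, the calcium buffer oncomodulin, at 95.03 against 13.7 CPM. Those for type II and extrastriolar hair cells had 3 higher, 1 lower and 5 neither (median 0.38), with Anxa4 at 483 against 89.7 CPM. Of 8 cochlear hair cell genes 4 were higher and 4 neither (median 0.42), with Strip2 at 31.1 against 5.66 CPM. Of 4 measured genes of multiciliated cells 3 were higher and 1 lower (median 1.60), with Foxj1, a regulator of motile cilia, at 146 against 44.2 CPM.

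Genes with the highest ratios in GFP high, at 50 CPM or more, were in part hair cell markers. Rasd2 stood at 362 against 32.0 CPM, Pvalb, a calcium buffer, at 584 against 65.8 CPM, and Slc52a3, a riboflavin transporter, at 56.8 against 3.73 CPM. Mogat1, Gm30191, Clec18a and Defb25 had ratios of 6.65 to 10.2. Lor, which codes for a protein of the horny layer of skin, had the highest ratio in this group, 168 against 2.56 CPM, and 98.9% of its GFP high UMIs lay in 10 cells.

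Other cell types and division marked the GFP low library. Of 13 neuron markers 0 were higher, 7 lower and 6 neither (median log2 ratio -1.01, percentile 0), with Tubb3, a neuronal tubulin, at 158.5 against 748 CPM and Stmn2 at 120 against 588 CPM. Neural progenitor markers had 5 of 6 lower and 1 neither (median -1.54), and mesenchyme markers 7 of 8 lower and 1 neither (median -1.48), with Col1a1, a fibrillar collagen, at 50.9 against 148 CPM. All 6 measured pluripotent markers were lower (median -3.81), and Pou5f1, which maintains pluripotency, stood at 2.04 against 51.0 CPM and Dppa5a at 12.2 against 461 CPM. Muscle markers had 5 of 6 lower (median -1.66), where 96.8% of the Acta1 UMIs and 74.5% of the Mylpf UMIs of GFP low lay in 10 cells. The lens crystallin genes Cryaa, Cryge and Cryba1 had the lowest ratios of the genes at 50 CPM or more, and more than 99% of their GFP low UMIs lay in 10 cells each. Of 20 cell cycle genes 16 were lower, 1 higher and 3 neither (median -1.74, -1.80 to -1.71, percentile 0), with Top2a, which untangles replicated DNA, at 17.8 against 78.7 CPM and Mcm5 at 4.45 against 29.0 CPM. At an equal depth of 3000 UMIs, 1.59% of GFP high cells (1.19 to 2.07%) and 5.32% of GFP low cells (4.61 to 6.101%) had an Mki67 or Top2a UMI, and 7.31% and 11.1% without thinning. Hair cells are postmitotic, so the share of hair-cell-like cells is given as background: 0.586% and 0.865% at 3000 UMIs (median depths before thinning 29976 and 25327 UMIs), against 3.88% and 6.25% in all other cells. Without thinning hair-cell-like cells gave 5.38% and 6.675%.

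Few members of the supporting cell list and of several other lists passed the size rule between the gates, although supporting-cell-like cells were 18.1% of GFP low and 8.88% of GFP high. An unnamed cluster with supporting cell markers (66.7% raised) beside hair cell markers held 4.25% of GFP high and 0.136% of GFP low. It adds supporting cell RNA mainly to GFP high, by an amount not measured here. Supporting cell markers had 0 higher, 1 lower and 12 neither of 13 (median log2 ratio -0.17, -0.21 to -0.14, percentile 10.9; -0.39 as a mean of per-cell CPM). Hes5, a Notch target, was the lower one at 15.8 against 33.4 CPM. Notch pathway genes had 3 higher, 1 lower and 12 neither of 16, with a median of -0.19 but a mean of 0.10, and the ligand Jag2 stood at 136 against 37.6 CPM. Otic epithelium markers had 1 of 11 higher, 1 lower and 9 neither (median -0.11), and the regulator Pax2 was the higher one at 97.46 against 45.6 CPM. Acellular membrane and otolith matrix genes had 10 of 10 neither (median -0.14), and Wnt targets 1 higher, 1 lower and 3 neither of 5 (median -0.26). Retinoid pathway genes had 2 of 9 lower and 7 neither (median -0.09), with the binding protein Crabp1 at 32.2 against 160.0 CPM. Glycolysis and hypoxia genes had 1 of 15 lower and 14 neither (median -0.06). Glia or neural crest markers had 1 higher, 1 lower and 4 neither of 6 (median -0.56), cartilage markers 1 lower and 5 neither of 6 (median -0.58), and epidermis markers 8 of 8 neither (median -0.46, percentile 0.25). Dissociation stress genes had 14 of 14 neither (median -0.47, percentile 0.01), and the 1 measured endothelium marker was neither (-0.46), while no melanocyte or blood marker reached 10 CPM in either library.

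The median log2 ratio of all genes was -0.04 with CPM and 0.09 with TMM scaling, a shift by which the otic epithelium (0.01), retinoid (0.03) and glycolysis and hypoxia (0.06) medians turned positive and Hes5 was no longer lower by the size rule. Atoh1 had a log2 ratio of 3.15 without the Ccer2-rich clusters 1 and 26 and 1.497 as a mean of per-cell CPM, which also gave a cell cycle median of -1.15.

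**Figure D2:**
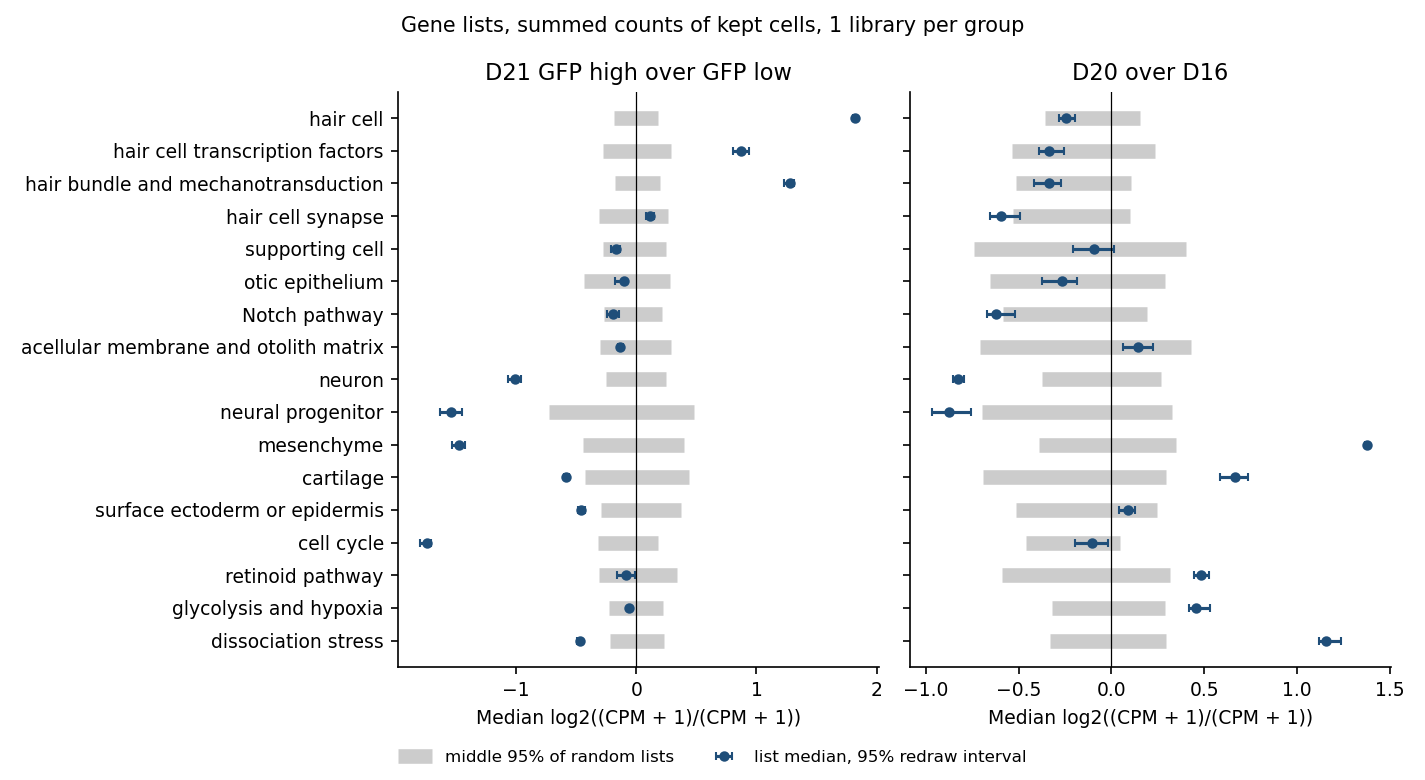
Median log2 ratio of CPM (horizontal axis) for 17 gene lists (vertical axis), GFP high over GFP low on the left and day 20 over day 16 on the right, with 95% redraw intervals and, in grey, the middle 95% of random lists. Hair cell markers had 1.82 on the left and -0.24 on the right; the right panel's medians sit against an all-gene median of -0.19.

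Within hair-cell-like cells at day 21, those of the GFP high library held more RNA of Atoh1, of 12 of 22 hair cell markers and of 4 of 10 Notch pathway genes, and those of GFP low more RNA of Bmp2, Olfm4, Adam11 and 3 of 6 retinoid genes, while bundle genes were nearly level. This comparison addresses differences inside 1 class, apart from its share but not apart from the mix of its clusters. Only Atoh1, Egfp and the bundle list were also compared with the cluster weights of GFP low in both libraries, so the other values may reflect that mix. Atoh1 stood at 173.0 against 34.1 CPM (ratio 5.075, 4.70 to 5.48) and Nhlh1, an early neuronal and hair cell transcription factor, at 53.8 against 9.30 CPM. Of 22 hair cell markers 12 were higher and 10 neither (median log2 ratio 1.05, 1.03 to 1.07), with Gng8 at 185 against 30.8 CPM. Of 24 bundle genes 1 was higher and 23 neither (median -0.04, -0.07 to -0.01, with a mean of 0.03), the higher one being Grxcr1 at 154.5 against 76.1 CPM.

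Notch pathway genes had 4 of 10 higher and 6 neither within this class (median 0.76, 0.67 to 0.90, percentile 100). The ligands Dll3, at 52.0 against 11.5 CPM, and Jag2, at 171 against 74.4 CPM, were higher, as were the glycosyltransferase Mfng, at 61.9 against 18.01 CPM, and Hes6, at 167 against 78.7 CPM. Type II and extrastriolar genes had 3 higher, 1 lower and 3 neither of 7 (median 0.60), and cochlear hair cell genes 3 higher and 4 neither of 7 (median 0.68). Type I and striolar genes went both ways, with 2 higher, 3 lower and 5 neither of 10 (median -0.59, percentile 0): Ocm stood at 147 against 60.8 CPM and Cyp26b1, which degrades retinoic acid, at 27.6 against 63.9 CPM. Retinoid pathway genes had 1 higher, 3 lower and 2 neither of 6 (median -0.96, percentile 0), with the retinoic acid receptor Rarb at 97.7 against 215 CPM and the retinal reductase Dhrs3 at 187 against 399.8 CPM. Bmp2 (chromosome 2, 133552159 to 133562885, plus strand), a secreted signal of the BMP family, stood at 41.5 against 340.2 CPM, Olfm4 at 19.9 against 162 CPM and Adam11 at 25.7 against 185 CPM. Other genes with the highest ratios included S100b at 80.4 against 11.3 CPM, Mdk, a growth factor, at 334 against 52.4 CPM, and Mcm6 at 138 against 22.9 CPM. Wfdc18 had the lowest ratio, 3.59 against 69.7 CPM, with 99.8% of its GFP low UMIs in 10 cells.

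The class was made up of 5 clusters that the gates held in different proportions. A cluster led by Bmp2, Olfm4 and Adam11 held 38.6% of the class in GFP low (318 cells) and 4.03% in GFP high (90 cells). An Atoh1-rich cluster led by Grp, Pvalb and Mcm6 held 6.31% of the class in GFP low (52 cells) and 22.2% in GFP high (495 cells). A cluster led by Cib3, with Kcna10 and Cabp2, held 45.4% and 36.1%, that led by Ocm and Strip2 6.68% and 20.1%, and that led by Pvalb and Calb2 3.03% and 17.6%. Between the same clusters of the gates the Atoh1 ratio was 1.30 (0.824 to 1.99) in the Bmp2 cluster, 1.34 in the Grp cluster, 1.37 in the Cib3 cluster, 1.43 in the Pvalb and Calb2 cluster and 3.20 (2.39 to 4.37) in the Ocm cluster. The bundle median changed sign, to 0.13 without the 10 CPM minimum, 0.04 at resolution 2.0 and 0.15 with the cluster weights of GFP low in both libraries, so bundle genes have no firm direction here. Under TMM scaling Grxcr1 and Otof (1129 against 565 CPM) were no longer higher by the size rule.

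**Figure D3:**
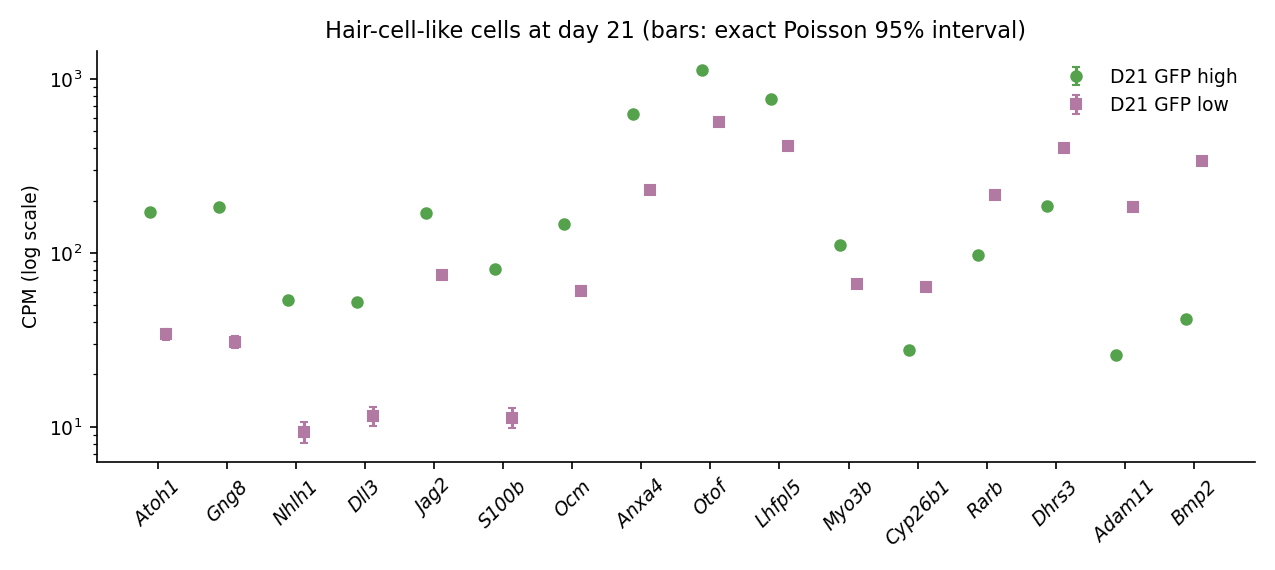
CPM on a log scale (vertical axis) of 16 genes (horizontal axis) summed over hair-cell-like cells of the day 21 GFP high (circles) and GFP low (squares) libraries, with exact Poisson 95% intervals as bars. Atoh1 stood at 173.0 against 34.1 CPM and Bmp2 at 41.5 against 340.2 CPM.

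Between days 16 and 20, 6 of 10 mesenchyme markers and 9 of 14 dissociation stress genes were higher in the day 20 library and 6 of 13 neuron markers lower, while 17 of 20 hair cell markers were neither. The comparison addresses how the organoids' cells differed between the days, and day cannot be separated from gate or processing run. The median log2 ratio of all genes was -0.19 (0.01 under TMM scaling), so list medians are also given relative to it. Of 10 mesenchyme markers 6 were higher, 1 lower and 3 neither (median 1.38, 1.57 relative to all genes, percentile 100), with the collagen gene Col1a1 at 2037 against 658 CPM, the matrix proteoglycan gene Dcn at 1542 against 479 CPM and Postn at 472 against 134 CPM. The days held different mixes of mesenchyme-like clusters, and the list was not compared within them. Of 14 dissociation stress genes 9 were higher and 5 neither (median 1.16, 1.35 relative, percentile 100), with the immediate-early genes Junb at 1590.0 against 336 CPM, Ier2 at 2502 against 693 CPM and Nr4a1 at 235.5 against 62.4 CPM. These stress genes moved with a lower median depth, 8836 against 15226 UMIs, and a lower median mitochondrial share, 0.922% against 2.60%. Glycolysis and hypoxia genes had 3 of 15 higher and 12 neither (median 0.46, 0.65 relative, percentile 99.8), with Bnip3 at 821 against 313 CPM and Ero1l at 249 against 79.9 CPM.

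Neuron markers had 6 of 13 lower and 7 neither at day 20 (median -0.82, -0.64 relative, percentile 0), with Tubb3 at 496 against 1201 CPM and Elavl3, an RNA-binding protein of neurons, at 72.5 against 195 CPM. Neural progenitor markers had 1 higher, 3 lower and 4 neither of 8 (median -0.87). Wnt targets had 3 of 7 lower and 4 neither (median -0.81, -0.62 relative), with the Wnt effector Lef1 at 5.22 against 25.7 CPM. Notch pathway genes had 1 higher, 2 lower and 9 neither of 12 (median -0.62, -0.43 relative), with Notch2 at 36.2 against 13.1 CPM and Jag2 at 19.4 against 45.9 CPM. Hair cell synapse genes had 1 of 13 higher and 12 neither (median -0.60), and the calcium-binding gene Cabp2 was the higher one at 37.9 against 18.4 CPM. Retinoid pathway genes had 2 higher, 1 lower and 4 neither of 7 (median 0.48, 0.67 relative), and cartilage markers 2 of 6 higher and 4 neither (median 0.67, 0.85 relative), where 68.5% of the day 20 UMIs of Cnmd, one of the higher ones, lay in 10 cells.

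Hair cell markers had 0 higher, 3 lower and 17 neither of 20 (median -0.24, -0.28 to -0.19, percentile 13.02), which is -0.06 relative to all genes. Relative to all genes the sign turned positive as means of per-cell CPM (-0.04 against -0.20) and without the 10 CPM minimum (-0.09 against -0.19), so these markers have no firm direction. Atoh1 stood at 155 CPM at day 20 and 129 CPM at day 16 (ratio 1.20, 1.16 to 1.24; log2 0.26), but without the Ccer2-rich clusters 1 and 26 its log2 ratio was -1.22, so its direction rests on them. Epidermis-like cluster 27, with Ccer2 at 16643 CPM, Atoh1 at 500 CPM and 89 of its 95 cells from day 16, was not left out. Pou4f3 stood at 131 against 188 CPM and Rasd2 at 18.5 against 69.3 CPM. Ccer2 (chromosome 7, 28756174 to 28758968, plus strand), a hair cell marker on the list, stood at 17467 against 10061 CPM. Supporting cell markers had 1 of 7 lower and 6 neither (median -0.09, -0.20 to 0.01, percentile 75.8), and the cell cycle list 1 of 20 lower and 19 neither (median -0.10, percentile 79.3). Cells with an Mki67 or Top2a UMI were 5.55% at day 16 (4.77 to 6.43%) and 3.88% at day 20 (3.28 to 4.54%) at 3000 UMIs, and 11.1% and 5.93% without thinning. At 3000 UMIs hair-cell-like cells gave 1 of 187 cells (0.535%) at day 16, and 0 of 142 cells at day 20, which allows a share of up to 2.11% at that depth by 3 counts and 2.56% by the exact interval. Their median depths before thinning were 33052 and 17288 UMIs, and without thinning they gave 9.95% (19 of 191 cells) and 4.795% (7 of 146 cells).

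Among genes with the highest ratios at day 20, Spp1, the gene of osteopontin, stood at 504 against 23.4 CPM, Igfbp7 at 398 against 36.2 CPM and the chemokine Cxcl12 at 491 against 52.7 CPM. Car3, a carbonic anhydrase, stood at 183 against 4.10 CPM, and Lcn2 at 61.8 against 0.157 CPM with 51.1% of its day 20 UMIs in 10 cells. Igfbp7 and Cxcl12 are leading genes of mesenchyme-like cluster 0, with 1582 of its 1612 cells from day 20. Car3 and Spp1 are leading genes of unnamed cluster 21, with 170 of its 211 cells from day 20. Their ratios may thus reflect clusters found mostly in 1 library. Among genes with the lowest ratios were Lhx2 at 23.8 against 132.5 CPM, Lhx9 at 8.79 against 67.3 CPM and Ebf3 at 28.5 against 129 CPM, and the cyclin gene Ccnd1 at 26.7 against 109 CPM. Dppa5a had the lowest ratio, 8.98 against 80.0 CPM, with 98.8% of its day 16 UMIs in 10 cells. Relative to all genes the supporting cell median was 0.09, the cell cycle median 0.08 and the type I and striolar median 0.03 (-0.16 with CPM). Under TMM scaling Wnt targets had 1 of 7 lower, Notch pathway genes 2 higher and 1 lower of 13, neural progenitor markers 2 higher and 2 lower of 7, retinoid genes 3 of 7 higher and 0 lower, hypoxia genes 5 of 15 higher and neuron markers 5 of 13 lower. There Cyp26b1, Gata3, Rfx3, Ush1c, Mfng and Apcdd1 were no longer lower by the size rule.

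Within hair-cell-like cells, the day 20 library held more RNA of 5 of 10 type I and striolar genes than the day 16 library, and less of 6 of 12 neuron markers, part of which rested on few cells. These values rest on 146 and 191 cells, and the median log2 ratio of all genes was -0.11. Type I and striolar genes had 5 higher, 1 lower and 4 neither of 10 (median 0.73, 0.60 to 0.89), with the potassium channel gene Kcna10 at 256 against 37.4 CPM and Cabp2 at 635 against 165 CPM. Both are leading genes of the Cib3 cluster, which held 4.19% of the class at day 16 and 39.7% at day 20. The list was not compared within clusters, so its rise may reflect that mix. Spp1 stood at 455 against 11.1 CPM and Ocm at 94.7 against 33.1 CPM, with 97.9% and 96.2% of their day 20 UMIs in 10 cells. Hypoxia and glycolysis genes had 3 of 15 higher and 12 neither (median 0.48), with Bnip3 at 1995 against 581 CPM. Atoh1 stood at 212 against 304 CPM (ratio 0.698, 0.633 to 0.769), but inside clusters the ratio was 1.24 (1.09 to 1.40) in the Grp cluster, 1.325 (1.06 to 1.65) in the Pvalb and Calb2 cluster and 0.456 (0.291 to 0.683) in the Ocm cluster. In the Cib3 cluster, which is low in Atoh1 (36.1 against 33.6 CPM), it was 1.07 (0.441 to 3.15). The log2 ratio of Atoh1 in the class was 1.24 at resolution 2.0 and 0.44 with the class set by marker genes, so Atoh1 has no firm direction here. Hair cell transcription factors had 1 higher, 1 lower and 8 neither of 10 (median -0.49), with Insm1 at 14.1 against 60.5 CPM.

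Neuron markers had 6 of 12 lower and 6 neither within this class (median -0.90), otic epithelium markers 2 higher and 4 lower of 6 (median -1.20) and Notch pathway genes 2 of 12 lower and 10 neither (median -0.48). Of the day 16 UMIs, 10 of 191 cells held 92.8% for Neurod1, 72.5% for Tubb3, 71.5% for Gap43, 61.3% for Elavl3, 100% for Oc90 and 70.7% for Otol1, all among the lower ones. Sox11, a transcription factor of immature cells, stood at 24.5 against 165 CPM and Id2 at 12.4 against 90.1 CPM, while Ccnd1 stood at 4.01 against 93.0 CPM with 71.1% of its day 16 UMIs in 10 cells. Bundle genes had 2 higher, 1 lower and 20 neither of 23 (median 0.32, 0.24 to 0.48, percentile 99.4), with the higher gene Fscn2, an actin bundler, at 180.2 against 59.4 CPM and the lower gene Pcdh15, a tip link cadherin, at 32.9 against 116 CPM. The class was again mixed, since the Cib3 cluster held 4.19% of it at day 16 (8 cells) and 39.7% at day 20 (58 cells), and the Grp cluster 54.5% (104 cells) and 26.7% (39 cells). The bundle median was -0.20 in the Grp cluster alone and -1.36 at resolution 2.0, where Ccer2-rich cells joined the class, and it was 0.14 with doublets kept and 0.19 with the class set by marker genes.

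Reporter RNA was not limited to clusters rich in Atoh1. Summed over the 4 libraries, whose gates and cluster shares differ, the Grp cluster of hair-cell-like cells had 9320 CPM of Egfp and 431 CPM of Atoh1, the supporting-cell-like cluster 4146 and 45.6 CPM, and the Bmp2 cluster 730 and 9.29 CPM. A cluster named neural-progenitor-like, led by Fabp7 but also by Gfap and Aqp4, which that list does not hold, had 7601 CPM of Egfp with 48.6 CPM of Atoh1. By library, its Atoh1 was 132 CPM in GFP high, 47.7 CPM at day 20 and 0 in GFP low, and its Egfp was above that of the Grp cluster at day 16 (14077 against 6493 CPM, 17 cells) and in GFP high (12027 against 9961 CPM, 20 cells) but below it at day 20 (7407 against 14505 CPM) and in GFP low (3131 against 5740 CPM). An unnamed cluster led by Car3, T and Lgals3, found mostly at day 20 (3.91% of day 20 cells), had 5818 CPM of Egfp with 4.23 CPM of Atoh1. In 10 of 11 clusters with 50 or more cells in both day 21 libraries Egfp was higher in GFP high beyond counting error, with ratios up to 7.14 in a neuron-like cluster, and in the other, an epidermis-like cluster, the ratio was 1.06 (0.952 to 1.18). These libraries were sorted on GFP, so that direction follows from the gate and is no separate result. The highest Atoh1 level, 762 CPM, was in an unnamed cluster whose leading gene was Ccer2, at 85794 CPM, and which held 10.1% of cells at day 16 and 16.6% at day 20, but 1.95% of GFP high and 3.74% of GFP low.

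**Figure D4:**
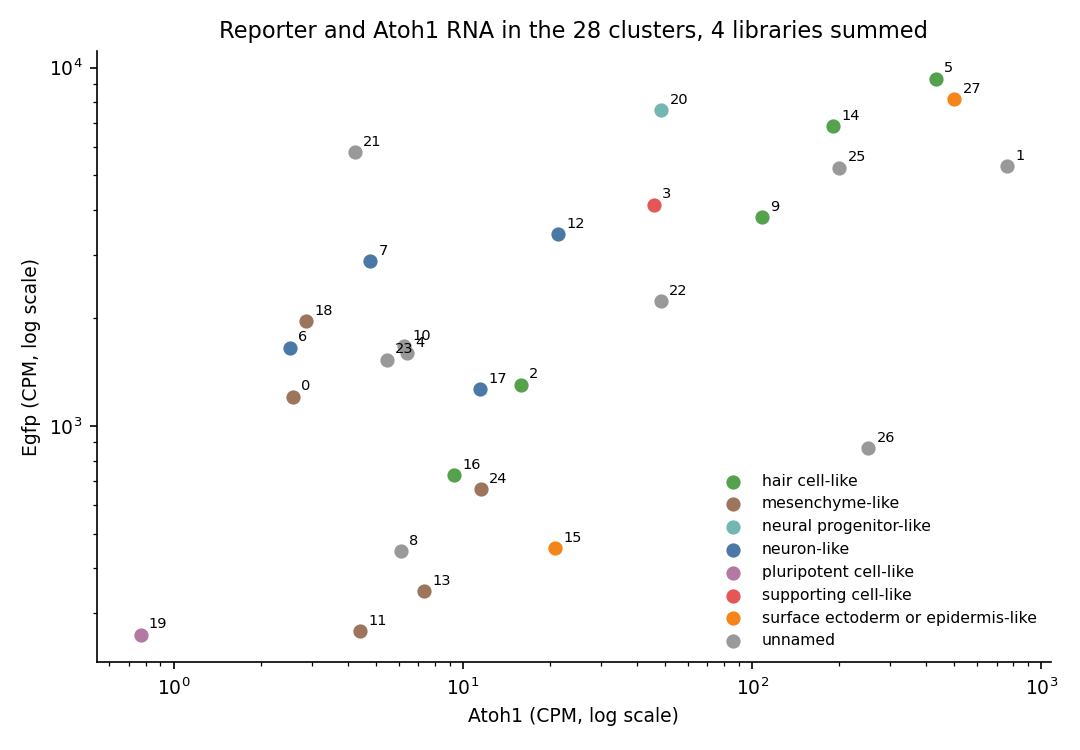
Egfp CPM (vertical axis, log scale) against Atoh1 CPM (horizontal axis, log scale) for the 28 clusters with the 4 libraries summed, each point a cluster, numbered and coloured by class. Clusters 20 and 21 had 7601 and 5818 CPM of Egfp at 48.6 and 4.23 CPM of Atoh1, and cluster 1 had 762 CPM of Atoh1.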

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

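Of 150 alternatives to 23 results, 73 kept the value within its counting interval, 67 moved it and 10 reversed the sign of a value whose interval excluded 0. The 18 alternatives that left out clusters 1 and 26, gave both libraries the same cluster weights, took cluster 5 alone or concern Atoh1 between the days were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and no library could be left out for the same reason. Counting intervals are narrow at these depths, so small moves pass them; where none is named, the cause was not tested. The day 16 and day 20 supporting-cell-like shares rest on 20 and 17 cells and within-class values on 146 to 2232 cells. Medians below are log2 ratios, GFP for high over low and days for day 20 over day 16. Shares are in percent, in the order day 16, day 20, GFP high, GFP low where 4 are given.

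With all deposited barcodes, the hair cell median was 1.72 (GFP), the supporting cell medians -0.23 (GFP) and -0.30 (days), hair-cell-like shares 4.65, 2.78, 61.0 and 20.8, and supporting-cell-like shares 7.23 (GFP high) and 14.9 (GFP low). With at least 2000 genes and at most 10% mitochondrial UMIs, the hair cell medians were 2.06 (GFP) and -0.19 (days) and the supporting cell median -0.13 (GFP). With no doublets removed, the hair cell median was 1.79 (GFP), the supporting cell median -0.32 (days), the hair bundle medians within hair-cell-like cells -0.0044 (GFP) and 0.14 (days), and hair-cell-like shares 3.40, 2.66, 58.8 and 20.5.

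With TMM scaling, which multiplies all genes of a library by a constant and so also changes which pass the 10 CPM minimum, the hair cell medians were 1.94 (GFP) and -0.057 (days), the Atoh1 log2 ratio 2.21, the cell cycle medians -1.62 (GFP) and 0.075 (days, reversed by the shift of all genes), the supporting cell medians -0.049 (GFP) and 0.25 (days, with 8 members in place of 7, positive where the reported value's interval spanned 0), and the bundle median -0.080 (GFP). As means of per-cell CPM, the hair cell medians were 1.69 (GFP) and -0.037 (days), the supporting cell medians -0.39 (GFP) and -0.30 (days), the cell cycle median -1.15 (GFP) and Atoh1 1.497. Without the 50 most abundant genes in the total, the supporting cell median was -0.26 (days). A pseudocount of 0.1 gave a cell cycle median of -1.83 (GFP). Without the 10 CPM minimum, the supporting cell medians were -0.13 (GFP) and -0.25 (days), the hair cell median -0.087 (days) and the bundle median 0.13 (GFP, reversed). Without clusters 1 and 26, which are rich in Atoh1 and Ccer2 and held 16.6% and 1.89% of day 20 cells, the hair cell medians were 1.95 (GFP) and -0.40 (days) and Atoh1 3.15 (GFP) and -1.22 (days, reversed from 0.26).

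Within hair-cell-like cells Atoh1 between the days, -0.52 as reported, reversed to 1.24 at resolution 2.0, 0.44 with the class set by marker genes and 0.31 in cluster 5 alone. With the cluster weights of GFP low in both libraries the bundle median was 0.15 (GFP, reversed), and in cluster 5 alone -0.20 (days, reversed). At resolution 2.0, where Ccer2-rich cells joined the class, the bundle medians were 0.039 (GFP, reversed) and -1.36 (days, reversed), hair-cell-like shares 3.94, 17.5, 60.03 and 24.2, and the supporting-cell-like share 7.80 (GFP high). At resolution 0.5 no cluster was named supporting-cell-like, so that setting gave no value for it. With the class set by marker genes, the bundle medians were -0.074 (GFP) and 0.19 (days). With each library clustered alone, supporting-cell-like shares were 0, 0, 7.42 and 9.39 and the hair-cell-like share of GFP high 62.4. With 4000 variable genes, hair-cell-like shares were 18.4 (day 20) and 24.7 (GFP low). Shares of cells with an Mki67 or Top2a UMI were 7.01, 4.80, 2.31 and 6.25 at 5000 UMIs and 11.1, 5.93, 7.31 and 11.1 without thinning, as deeper cells hold more UMIs, and 4.51 at 2000 UMIs (GFP low). In each setting tried, hair cell medians were positive for GFP and negative for days, hair-cell-like shares were higher in GFP high than in GFP low, and cycling shares lower. Relative to the all-gene median of the same setting, the hair cell median of days turned positive as means of per-cell CPM (-0.037 against -0.20) and without the 10 CPM minimum (-0.087 against -0.19), so it has no firm direction.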

Other observations

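All tests of explanations in this part were chosen after the results they measure had been seen. Supporting-cell-like cells of day 21 (305 in GFP high and 667 in GFP low) differed in reporter RNA and in some hair cell markers. The medians of hair cell and neuron markers in this class go the way of library make-up. Hair-cell-like cells were 65.0% of GFP high and 22.4% of GFP low, and neuron-like cells 5.85% and 24.6%. Free RNA and doublets were not tested for this class, so the values may not be expression of its cells. In this class Egfp stood at 6416 CPM in GFP high and 2569 CPM in GFP low, and Atoh1 at 58.2 and 36.6 CPM (ratio 1.59, 1.40 to 1.81). Of 17 hair cell markers 5 were higher, 1 lower and 11 neither (median log2 ratio 0.65, 0.55 to 0.77), with Pou4f3 at 107.5 against 49.4 CPM and Rasd2 at 91.6 against 38.2 CPM. Among the higher ones, 10 cells held 69.3% of the Pvalb, 50.3% of the Otof and 84.05% of the Lhx3 UMIs of GFP high. Supporting cell markers had 1 of 13 higher and 12 neither (median 0.34), with Tectb, a protein of the tectorial and otolithic membranes, at 257 against 104 CPM and 74.0% of its GFP high UMIs in 10 cells. Notch pathway genes had 15 of 15 neither (median 0.26).

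Several named genes were lower in the supporting-cell-like cells of GFP high. The metallothionein gene Mt1 stood at 345.5 against 1079 CPM, Ndrg1 at 86.9 against 216 CPM, and Egln3, an oxygen-sensing hydroxylase, at 70.1 against 161 CPM. Of 15 glycolysis and hypoxia genes 1 was lower and 14 neither (median -0.44, -0.45 to -0.41), with Ero1l at 177 against 389 CPM. Neuron markers had 5 of 7 lower and 2 neither (median -1.83), with Elavl4 at 3.47 against 23.2 CPM and 79.7% of its GFP low UMIs in 10 cells.

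Hair-cell-like cells of GFP low held less Atoh1 than those of GFP high (ratio 5.075). With the cluster weights of GFP low in both libraries the ratio was 1.48, which is consistent with a different mix of hair-cell-like clusters as the larger part, although Atoh1 helped to define those clusters. Whether GFP low cells stand later in time stays open: across 4315 genes, which are not independent replicates, their log2 ratios over GFP high and those of day 20 over day 16 had a Spearman rho of 0.212 (0.166 over 9865 genes at 10 CPM), too weak to tell, and day cannot be separated from gate and run. The gate itself selects on the reporter of Atoh1, so lower Atoh1 in GFP low may follow from the sort. Inside each hair-cell-like cluster Egfp was higher in GFP high, with ratios from 1.365 in the Cib3 cluster to 3.84 in the Ocm cluster. The mix of clusters may itself be an outcome of the gate, so mix and gate cannot be told apart here.

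Clusters 20 and 21 held Egfp at 7601 and 5818 CPM with 48.6 and 4.23 CPM of Atoh1, summed over libraries. Free RNA is argued against, since in the day 20 library Egfp was 111 times (88.0 to 143) as high in these clusters (6888 CPM) as in mesenchyme-like cluster 13 (61.8 CPM), the lowest there, and still 5.64 and 3.66 times (3.30 to 4.06) as high as in mesenchyme-like clusters 0 and 18, the highest of that class. Doublets with Atoh1-rich hair-cell-like cells are argued against as well, since Pou4f3 stood at 9.11 CPM, 1.51% of the 604 CPM that the Egfp level would need. The clusters differ in Atoh1, however. That of cluster 20 (48.6 CPM) lay above hair-cell-like clusters 2 and 16 (15.8 and 9.29 CPM) and near the supporting-cell-like cluster (45.6 CPM). There 4 of 16 hair cell markers outside the bundle list, Atoh1 and Ccer2 were raised, against 0 in cluster 21. A reporter that goes with Atoh1 stays open for cluster 20. Reporter RNA that outlasts Atoh1, or a reporter active without it, may account for the values, above all in cluster 21, and was not tested.

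Cluster 1 and the shallow cluster 26 held Ccer2 at 85794 and 113382 CPM with Atoh1 but few raised hair bundle genes (3 and 6 of 23, against 19 in hair-cell-like cluster 5). The bundle gene Espn stood at 695 CPM in cluster 1 and 574 CPM in cluster 5, but Myo7a at 1.77 against 130 CPM and Lhfpl5 at 81.8 against 745 CPM. Merkel cells, touch receptors of skin that also express Atoh1, are a candidate source. Of 13 measured genes of a Merkel cell list, 10 (76.9%) were raised in cluster 1, against at most 4 in a hair-cell-like cluster. That list was not among the 28 and was chosen after the clusters had been seen. Of the 10, 3 are on other lists (Atoh1, Sox2 and Isl1), and Atoh1 is part of the pattern itself. Isl1, Piezo2 and Chga were already leading genes of cluster 1 or cluster 26, so the count is not independent support. Syp, Ncam1 and Eno2 were not raised in cluster 1. Epidermis-like cluster 27 had 6 of the 13 raised, with Pou4f3 and Lhx3 also raised and Otof at 0 CPM. The list's abundant members in cluster 1 were Krt8 at 2104 CPM, Isl1 at 1313 CPM, Chga at 974 CPM, Krt18 at 896 CPM and Krt20 at 175 CPM. Egfp stood at 5302 CPM in cluster 1, summed over the libraries, yet the cluster was 1.95% of GFP high and 3.74% of GFP low. Reporter RNA is not GFP protein, so how a sort on GFP treats such cells was not tested. Cells as in cluster 5 would need like levels of 16 hair cell markers outside the pattern. Pvalb (4.15 against 1382 CPM), Otof (8.24 against 592 CPM) and Calb2 (13.5 against 794 CPM) were far lower in cluster 1, but Lhx3 (397 against 402 CPM) and Pou4f3 (536 against 807 CPM) were near. The median log2 ratio was -2.60 (-4.11 to -0.59 over members). Ocm, nearly absent from both clusters (0.122 against 0.580 CPM), counts there as a near level. The interval is a spread over a chosen list of genes, not over samples, so it cannot decide the question. Since this test was put in several forms, of which a count of raised markers (6 against 13) excluded such cells at a bare threshold but not beyond its interval, and the last interval crosses its bound of -1, a related hair cell state stays open and the Merkel name a hypothesis.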
